A study of Homo sapiens with 18 samples.

How the data were processed

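The deposited values were TPM per gene, transcript abundances scaled to the same total in each library, produced by the authors with Salmon and described by them as based on hg19. The version of Salmon and the annotation are not given in the sources used here. Total RNA had been prepared with a Qiagen kit, and libraries were made by Novogene. The table held 27800 genes and a column for each of the 18 libraries, with 0 columns of other samples and 0 pairs of identical libraries. Reads were not used here, so the sequencing depth, and the counting error of each value, is unknown. Mitochondrially encoded genes were not listed, and the genes MIR6723 and MIR4461 together held a large share of the TPM.

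The groups followed the labels: 3 transductions at 2 days with 3 libraries each. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these samples. The control role of ev was set in the design before the data were examined, as were the comparisons, the rule for naming genes, the lists and the alternatives, apart from those said below to have been added.

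Values were used as log2(TPM + 1), and 14685 genes with a TPM of at least 1 in at least 3 libraries were tested. A linear model with 6 group means was fitted with limma 3.58.1 in R 4.3.3, with moderated variances that followed the mean and were robust to unusual genes. P-values were adjusted with the Benjamini-Hochberg method within each comparison, and genes with an adjusted p below 0.05 were called. Comparisons were day 2 against day 0 in each transduction, each guide against ev at each day, the difference of each guide from ev in the change over time, and sg2 against sg1. Genes were counted for both guides when called in the same direction with each.

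A total of 32 gene lists from general knowledge, with 608 genes, was fixed beforehand. Of these genes 555 matched as listed, 37 matched by an older symbol, 16 did not match, and 521 were tested. Lists with at least 5 tested members, 26 in number, were tested with camera from limma at a preset correlation of 0.01, with adjustment over the lists of each comparison. The preset value takes genes of a list to be nearly independent, so the adjusted p with a correlation estimated from the data is given beside it. Alternatives were log2(TPM + 0.1), no filter, a stricter filter (a TPM of at least 5 in at least 3 libraries), median of ratios scaling, leaving out the 10 highest genes, the replicate number as a block, library weights, no trend or robust step, only the libraries compared, a log2 fold of at least 1, each library left out in turn, and for lists the estimated correlation and fry. Library weights computed gene by gene, and fits without library 3 of sg1 at day 0 with and without scaling, were added after the data were examined. Named genes followed a fixed rule. BCL2L1 was named in every comparison, and for each comparison the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 TPM in the higher group and all 3 libraries of 1 group above all 3 of the other, without the last condition for interactions. Non-coding and clone symbols were passed over. For both guides genes were ranked by the smaller of the guides' differences. From each list described up to 3 members with the smallest p in the direction of most called members and up to 2 in the other direction were taken, or the 2 with the highest TPM where none was called, and fewer could be named in that order. Folds refer to TPM + 1, and errors are standard deviations.

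Transcript lengths, GC content and gene order came from GENCODE 29 on GRCh38, and a length was found for 14095 tested genes (96.0%). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for preparation and figures. A self-test of the comparison of sg1 with ev at day 2 used simulated values, not the measured libraries. Log2 changes of 1 put into 100 genes were called in 48% and changes of 2 in 92%, while 6 other genes were called (4.11% of the calls). Genes with a low mean were not changed, so these shares do not apply to them. For lists, a list was shifted among simulated independent genes, 26 lists were tried and 0 others were called. That 0 does not show how often lists of correlated genes are called falsely.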

Results

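RNA was sequenced from PANC-1 cells, an established human pancreatic tumour cell line, after 3 kinds of transduction. The ev cells served as the control in the design used here, and sg1 and sg2 cells carried CRISPR guides against BCL2L1, the gene of the anti-apoptotic protein BCL-XL. Cells were collected at day 0 and after 2 days in a medium poor in nutrients and oxygen, with 2.5 mM glucose, 0.5% serum and amino acids at 20% of the standard level. The labels give that growth protocol for the day 0 samples too, so the medium of the day 0 cells is uncertain. Each of the 6 groups held 3 libraries, 18 in all. The values were TPM, transcript abundances which sum to the same total in every library, so the sequencing depth is unknown. The table listed 27800 genes, of which 14685 reached a TPM of 1 in at least 3 libraries and were tested. A library held between 11114 and 13716 genes at a TPM of at least 1.

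Library 3 of sg1 at day 0 stood apart from the other 17. Its correlation with any other library, across tested genes on the log2 scale, was 0.772 to 0.872, while every other library reached at least 0.942 with a library of its own group. Ribosomal protein genes made up 27.4% of its TPM and between 9.19% and 12.7% in the other libraries. Transcripts of at most 858.5 nt stood 0.50 above those of at least 2806 nt in the library's median log2 deviation from all libraries, and the same difference lay between -0.10 and 0.11 in the others. The library was kept, and counts of called genes are given also without it, because it enlarged the spread that all comparisons share.

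**Figure D1:**
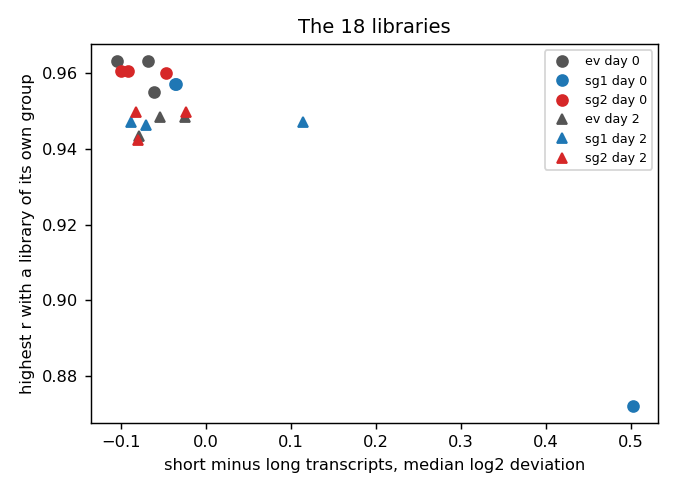
Each point is a library, with the median log2 deviation of short minus long transcripts on the x axis and the highest correlation with a library of the same group on the y axis. Library 3 of sg1 at day 0 lies at 0.50 and 0.872, away from the other 17.

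BCL2L1 itself was lower with both guides than in ev at both days, which is the gene the guides were directed against. At day 0 its mean was 185 ± 25.8 TPM in ev, 79.7 ± 8.15 in sg1 and 72.8 ± 14.3 in sg2 (SD, n = 3 in each group). At day 2 it was 96.3 ± 17.7, 45.5 ± 2.01 and 41.1 ± 3.20 TPM. The guide cells thus held 43.0% (sg1) and 39.2% (sg2) of the ev level at day 0, and 47.2% and 42.7% at day 2. The log2 difference from ev was -1.20 for sg1 (adjusted p = 2.88e-04) and -1.35 for sg2 (1.20e-04) at day 0. At day 2 it was -1.05 (0.00108) and -1.20 (3.55e-04). The 57 neighbouring tested genes from NINL to EIF6, around BCL2L1, were lower with both guides too in their median, but by less than BCL2L1. Their medians relative to all genes were -0.44 (sg1) and -0.42 (sg2) at day 0, and -0.51 and -0.40 at day 2. The values for BCL2L1 above are not relative to all genes. Each gene named here as among the largest differences between groups had all 3 libraries of 1 group above all 3 of the other. For BCL2L1 too all 3 guide libraries lay below all 3 ev libraries, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. BCL2L1 also fell over the 2 days, by 0.94 on the log2 scale in ev (adjusted p = 5.26e-04), 0.79 in sg1 (0.00221) and 0.79 in sg2 (0.00231). The change over time did not differ detectably from ev with either guide (0.15, adjusted p = 0.826 for sg1, and 0.15, 1.0 for sg2). In a fit of only the libraries compared the sg1 calls at day 0 and over time were lost (adjusted p = 0.0604 and 0.0574). TPM counts transcripts and does not show whether a transcript still encodes the protein, so the loss of BCL-XL was not measured here.

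**Figure D2:**
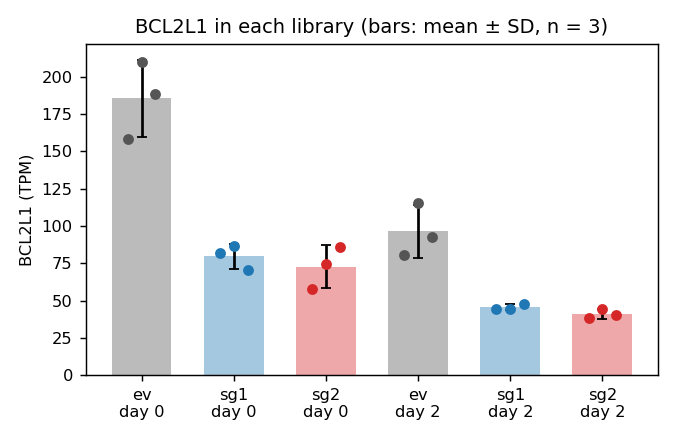
BCL2L1 in TPM by transduction and day, with bars for the mean, error bars for the SD of 3 libraries and a point per library. All guide libraries lie below the ev libraries of the same day, with means between 41.1 and 79.7 TPM against 96.3 and 185 TPM in ev.

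The change from day 0 to day 2 was read in ev cells, where time in culture and medium are not separated. DDIT4, which restrains growth signalling through mTORC1, rose from 15.9 ± 1.15 to 1055 ± 87.1 TPM (SD, n = 3 in each group), a 62.6-fold change on TPM + 1. NDRG1, a stress gene induced by low oxygen, rose 42.8-fold, and the stress transcription factor ATF3 rose 31.9-fold. NUPR1, a stress regulator, rose 30.5-fold, and HMOX1, which breaks down heme, rose from 82.4 ± 19.1 to 2091 ± 185 TPM. The largest falls were in the chemokine gene CXCL1 (log2 -3.45), the transcription factor gene NKX6-2 (-3.42) and the replication gene GINS2 (-3.35). Limma called 5168 genes (2824 higher, 2344 lower), and 8082 (4291 higher, 3791 lower) without library 3 of sg1 at day 0, which entered this comparison only through the shared spread.

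Among the fixed gene lists, the low-oxygen genes driven by HIF rose in ev in 27 of 28 (28 adjusted over the list alone), with a median log2 change of 2.59 (adjusted p = 3.04e-24 from the list test with a preset correlation, and 0.00353 with an estimated correlation). Besides DDIT4 and NDRG1 the list held PFKFB4, which steers glycolysis and rose from 1.96 ± 0.195 to 71.2 ± 5.56 TPM (SD, n = 3). NRF2 targets, which protect against oxidants, rose in 13 of 17 (13 adjusted over the list alone), with a median of 1.98 (3.54e-10, and 0.00353 with an estimated correlation). HMOX1, OSGIN1 (3.99) and NQO1 (2.49) led them. The ATF4 targets of the amino acid response rose in 22 of 24 (22 adjusted over the list alone), median 2.51 (adjusted p = 8.33e-20; adjusted p = 0.0631 with an estimated correlation). They included DDIT3 (3.67) and the mitochondrial enzyme gene PCK2 (4.46). Glycolysis genes rose in 14 of 18 (14 adjusted over the list alone), median 1.52 (adjusted p = 7.58e-09; adjusted p = 0.256 with an estimated correlation). PDK1, which inhibits pyruvate dehydrogenase, stood at 3.18.

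Most tested cholesterol synthesis genes rose in ev, and a minority of the tested genes of mitochondrial respiration fell. Cholesterol synthesis genes rose in 17 of 21 (17 adjusted over the list alone) with a median of 1.72 (adjusted p = 7.93e-10; adjusted p = 0.189 with an estimated correlation), led by STARD4 (3.33) and INSIG1 (2.99), which carry and sense sterols. Fatty acid synthesis genes rose in 6 of 11 (6 adjusted over the list alone), median 1.63 (adjusted p = 0.00212; adjusted p = 0.442 with an estimated correlation), and SCD, which desaturates fatty acids, reached 2012 ± 68.1 TPM from 120.4 ± 23.4 (SD, n = 3). Respiratory chain subunit genes fell in 9 of 30 (9 adjusted over the list alone), median -0.37 (adjusted p = 0.00112; adjusted p = 0.423 with an estimated correlation), with NDUFB10 at -1.60. Citric acid cycle genes fell in 7 of 18 (7 adjusted over the list alone), median -0.39 (adjusted p = 0.00904; adjusted p = 0.442 with an estimated correlation), with SUCLG1 at -0.92. Ribosomal protein genes had a median of 0.36 (adjusted p = 0.0212; adjusted p = 0.734 with an estimated correlation), with 8 of 30 higher (7 adjusted over the list alone) and RPL3 at 0.68, but this call was lost with median of ratios scaling (adjusted p = 0.299) and with the rotation test fry (0.0954).

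Most tested genes of cell division fell in ev, and most of the tested inhibitors of division rose. All 28 tested S phase genes fell in ev (28 adjusted over the list alone), with a median of -1.85 (adjusted p = 4.52e-19; adjusted p = 0.107 with an estimated correlation). GINS2 fell from 40.2 ± 5.09 to 3.15 ± 1.21 TPM (SD, n = 3), and RFC2 and FEN1, also needed to copy DNA, fell by 2.12 and 2.75 on the log2 scale. Mitosis genes fell in 22 of 30 (23 adjusted over the list alone), median -1.18 (adjusted p = 2.83e-09; adjusted p = 0.334 with an estimated correlation), with the mitotic kinase gene AURKB at -1.53. Cell cycle inhibitors rose in 14 of 20 (14 adjusted over the list alone), median 1.07 (adjusted p = 4.58e-06; adjusted p = 0.111 with an estimated correlation), led by CCNG2 (3.32) and BTG1 (2.48). MYC and ribosome assembly genes fell in 16 of 25 (17 adjusted over the list alone), median -0.77 (adjusted p = 1.62e-08; adjusted p = 0.0631 with an estimated correlation), with RRP9 at -1.91. Replication-dependent histone genes rose in 7 of 12 (7 adjusted over the list alone), median 0.94 (adjusted p = 0.0116; adjusted p = 0.279 with an estimated correlation), with HIST2H2BE at 2.58.

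Some NF-kB genes fell in ev, and other lists held genes that moved in both directions. NF-kB genes fell in 5 of 12 (6 adjusted over the list alone), median -0.43 (adjusted p = 0.0101; adjusted p = 0.296 with an estimated correlation), a call lost with a filter of a TPM of 5 in 3 libraries (0.0515), and the chemokine gene CCL2 fell from 228 ± 42.0 to 27.4 ± 9.92 TPM (SD, n = 3). Among the pro-apoptotic BCL2 family, BBC3 rose by 2.89, BMF by 2.95 and BCL2L11 by 1.85, while BID fell by 0.65, and the list of 9 as a whole was not called (median 0.24, adjusted p = 0.453). Endoplasmic reticulum stress genes split between HERPUD1 (2.19) and SEC61B (-1.27), with a median of -0.36 (0.208). The tRNA synthetase genes split between CARS (1.97) and FARSA (-1.60), with a median of 0.78 (0.208). The autophagy and lysosome list held the rising MAP1LC3B (2.44) and the falling ATG7 (-1.01), with a median of 0.12 (0.453). No call was made for p53 targets (median 0.17, adjusted p = 0.442), the ERK genes (-0.30, 0.394), interferon genes (-0.26, 0.144), antigen presentation (-0.15, 0.0715), mesenchymal genes (-0.07, 0.453), epithelial genes (0.76, 0.394) or the Notch pathway (0.05, 0.919).

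Cells with the guides changed many of the same genes over the 2 days. ATF3 rose 43.0-fold in sg1, NDRG1 37.7-fold and DDIT4 34.6-fold. In sg2, NDRG1 rose 56.9-fold and DDIT4 44.7-fold, to 753 ± 40.9 TPM (SD, n = 3). NKX6-2 fell most in both, by 4.63 and 4.51 on the log2 scale, followed in sg1 by the metallothionein MT1A (-3.53, but -2.81 and behind ID2 without library 3 of sg1 at day 0), and ID2, an inhibitor of differentiation factors, fell by 3.37 and 2.99. Limma called 5524 genes (3407 higher, 2117 lower) in sg1 and 4786 genes (2386 higher, 2400 lower) in sg2. Without library 3 of sg1 at day 0 these became 6902 (2980 higher, 3922 lower) and 7665 (3718 higher, 3947 lower), so that the majority of calls in sg1 went from higher to lower. The share of calls that were higher in sg1 was 61.7%, 43.2% without that library and 51.9% with median of ratios scaling. The median over all genes in sg1 was 0.19 and became -0.04 without the library. In all 3 transductions 1818 genes rose and 1365 fell, and 2482 and 2881 without the library, so that this majority turned too.

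The HIF list rose in sg1 in 27 of 28 (27 adjusted over the list alone), median 2.56 (adjusted p = 1.65e-19, and 0.0152 with an estimated correlation), and in sg2 in 25 of 28 (26 adjusted over the list alone), median 2.40 (1.72e-23 and 0.00701). NRF2 targets rose by a median of 1.15 in sg1 (4.94e-06 and 0.0365) and 1.07 in sg2 (1.17e-07 and 0.0143), with HMOX1 at 3.58 and 3.86. The HIF and NRF2 calls over time held with an estimated correlation in all 3 transductions. Without library 3 of sg1 at day 0 the NRF2 calls with an estimated correlation were lost, at adjusted p = 0.0839 in ev, 0.0803 in sg1 and 0.113 in sg2. S phase genes fell in sg1 in 17 of 28 (18 adjusted over the list alone), median -0.88 (adjusted p = 5.90e-09; adjusted p = 0.314 with an estimated correlation), and in sg2 in 27 of 28 (28 adjusted over the list alone), median -1.53 (adjusted p = 1.27e-14; adjusted p = 0.144 with an estimated correlation). Mitosis genes fell in sg2 by a median of 1.03 (adjusted p = 6.94e-08; adjusted p = 0.354 with an estimated correlation) and in sg1 by 0.19 (adjusted p = 0.00858; adjusted p = 0.694 with an estimated correlation). The call in sg1 was lost without library 1 of sg1 at day 0 (adjusted p = 0.0696) or without library 1 of sg1 at day 2 (0.0753), and with fry (0.303). Cholesterol synthesis genes rose by a median of 0.88 in sg1 (adjusted p = 2.30e-04; adjusted p = 0.447 with an estimated correlation) and 1.28 in sg2 (adjusted p = 4.07e-08; adjusted p = 0.237 with an estimated correlation). ATF4 targets rose by 2.44 in sg1 (adjusted p = 1.90e-17; adjusted p = 0.0904 with an estimated correlation) and 2.42 in sg2 (adjusted p = 1.96e-19; adjusted p = 0.0667 with an estimated correlation). Antigen presentation genes fell by 0.42 in sg1 (adjusted p = 5.72e-04; adjusted p = 0.114 with an estimated correlation) and 0.35 in sg2 (adjusted p = 0.0186; adjusted p = 0.238 with an estimated correlation). TAP1, part of the transporter that supplies peptides for MHC molecules, stood at -1.42 and -1.5. The antigen presentation call in sg2 was lost with the filter of a TPM of 5 in 3 libraries (0.0595).

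**Figure D3:**
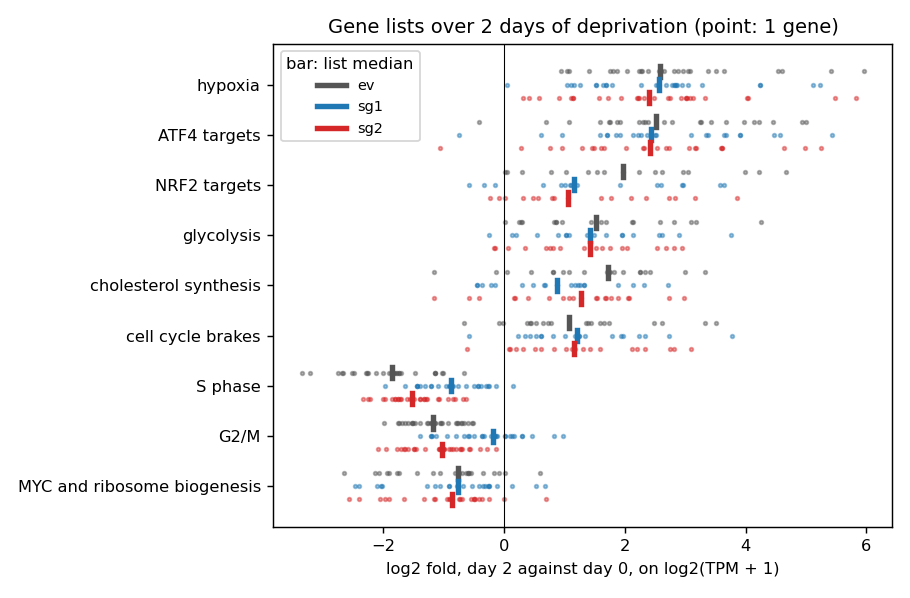
Log2 change from day 0 to day 2 for the tested genes of 9 lists in ev, sg1 and sg2, with a point per gene and a bar at the median of the list. The HIF medians are 2.59, 2.56 and 2.40, and the S phase medians are -1.85, -0.88 and -1.53.

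Guide cells were compared with ev at day 0 to ask how the transductions differed at the start. S100A16, a calcium-binding protein gene, was 93.0 ± 1.23 TPM in ev, 2.23 ± 1.31 in sg1 and 4.25 ± 1.96 in sg2 (SD, n = 3 in each group). DACT2, which modulates Wnt signalling, was lower, at log2 -3.80 with sg1 and -4.03 with sg2, as were the trypsinogen gene PRSS3 at -3.62 and -4.06 and the secreted glycoprotein gene FSTL1 at -3.47 and -3.47. Among the genes higher with both guides, ranked by the smaller of the guides' differences, ASB4 (1.71 and 1.95) came before the receptor gene TNFRSF18 (2.32 and 1.58). In a fit of only the libraries compared their sg1 calls were lost (adjusted p = 0.112 and 0.0713). With sg1 alone the largest rise was IGFBP2, a carrier of growth factors, at 274 ± 28.6 TPM against 24.5 ± 2.24 in ev and 11.6 ± 1.24 in sg2. With sg2 the largest were SHISA2 (2.52), KCNK1 (2.41) and the basement membrane collagen COL4A2 (2.19).

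For sg1 at day 0 limma called 1718 genes (797 higher, 921 lower), and 3024 (2108 higher, 916 lower) without library 3 of sg1. The majority did not keep its direction, with 3096 genes (1416 higher, 1680 lower) when scaling was added and 1955 (314 higher, 1641 lower) without the 10 highest genes. The count was 3229 without library 1 of sg1, and 1004, 960 and 824 without ev libraries 1, 2 and 3 in turn. In a fit of only the libraries compared it was 142 (34 higher, 108 lower). For sg2 limma called 708 genes (282 higher, 426 lower), and 2377 (1322 higher, 1055 lower) without library 3 of sg1. This count was 441 and 437 without ev libraries 2 and 3, and 454 and 430 without sg2 libraries 1 and 2. It was 3286 (1964 higher, 1322 lower) with only the libraries compared. Both guides shared 409 genes (122 higher, 287 lower), where independent calls would share 15.3 and 26.7. The shared count was 1405 (867 higher, 538 lower) without library 3 of sg1, 238 and 236 without ev libraries 2 and 3, and 271 without sg2 library 1. With only the libraries compared it was 162 (19 higher, 143 lower). With scaling as well as the library left out it was 1680 (696 higher, 984 lower), and without the 10 highest genes 433 (51 higher, 382 lower), so its majority was also not settled. Both comparisons use the same 3 ev libraries, which the figures for independent calls leave out of account. In 20 simulations with no guide effect the guides' changes correlated at 0.50, against 0.50 observed. The simulations gave a gene the same spread in every library, so the shared ev libraries set their value near 0.50 in advance. The likeness therefore does not show how much of the observed correlation came from those libraries. The covariance was 0.164 observed and 0.0961 simulated, from a spread that library 3 of sg1 had enlarged. The simulations shared 0 genes, but with no effect few genes are called at all. That 0 therefore does not measure the overlap that shared ev libraries can give.

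Mesenchymal genes were lower with sg1 at day 0, in 8 of 21 (13 adjusted over the list alone) members with a median of -0.93 (adjusted p = 4.08e-06; adjusted p = 0.396 with an estimated correlation). COL5A1, a fibrillar collagen, was 20.9 ± 2.51 TPM in ev and 1.5 ± 1.21 in sg1 (SD, n = 3), and MMP14 and CDH2 were lower, at log2 -1.35 and -1.05, calls lost in a fit of only the libraries compared (adjusted p = 0.115 and 0.234). Epithelial genes were higher with sg1 in 4 of 17 (6 adjusted over the list alone), median 0.23 (adjusted p = 0.0107; adjusted p = 0.396 with an estimated correlation), with EPCAM at 210.4 ± 48.6 TPM against 45.5 ± 3.53 in ev. They were higher with sg2 in 2 of 17 (7 adjusted over the list alone), median 0.59 (adjusted p = 0.00738; adjusted p = 0.451 with an estimated correlation), led by CDH3 (1.40). With sg2 the mesenchymal list divided, with CDH2 at 2.04 and COL5A1 at -2.72, and was not called (median -0.22, adjusted p = 0.528). NRF2 targets were higher with sg2 in 3 of 17 (8 adjusted over the list alone), median 0.64 (adjusted p = 4.60e-04; adjusted p = 0.158 with an estimated correlation), as were antigen presentation genes in 2 of 13 (5 adjusted over the list alone), median 0.45 (adjusted p = 5.96e-04; adjusted p = 0.172 with an estimated correlation). With sg1 antigen presentation genes were higher in 4 of 13 (6 adjusted over the list alone), median 0.29 (adjusted p = 0.00466; adjusted p = 0.396 with an estimated correlation), and endoplasmic reticulum stress genes in 5 of 18 (7 adjusted over the list alone), median 0.34 (adjusted p = 0.00138; adjusted p = 0.369 with an estimated correlation). The sg1 calls for respiratory chain subunits (median 0.52; adjusted p = 2.13e-05; adjusted p = 0.396 with an estimated correlation), NRF2 targets (0.33; adjusted p = 0.0356; adjusted p = 0.396 with an estimated correlation) and histones (0.45; adjusted p = 0.0139; adjusted p = 0.396 with an estimated correlation) were lost without library 3 of sg1, at adjusted p = 0.0834, 0.197 and 0.165. The NRF2 call was also lost without ev library 2 (0.0668), with median of ratios scaling (0.102) and with the filter of a TPM of 5 in 3 libraries (0.0590), and the histone call without sg1 library 2 (0.0794).

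The comparison of guide cells with ev at day 2 addressed how cells aimed to lack BCL-XL differ after the 2 days. IGFBP1, which binds insulin-like growth factors, reached 89.3 ± 9.84 TPM in ev, 0.158 ± 0.104 in sg1 and 1.75 ± 0.695 in sg2 (SD, n = 3 in each group). S100A16 was again lower, at log2 -4.50 with sg1 and -4.52 with sg2, and MT1M, a metallothionein, was listed at 0 in all 6 guide libraries and at 12 ± 2.63 TPM in ev. DACT2 was lower, at -3.54 and -4.06, and COL5A1 at -3.63 and -3.47. EGR1, an immediate early transcription factor downstream of ERK, was 3.95 ± 0.176 TPM in ev, 15.5 ± 3.21 in sg1 and 25.9 ± 11.7 in sg2. LPAR3, a lipid receptor gene, was higher too (2.05 and 1.76), but its sg2 call was lost in 4 of 6 leave-one-out fits, at adjusted p up to 0.116. The largest differences with sg1 alone included TMEM255A (2.93) and IGFBP2 (2.87).

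Limma called 1134 genes (441 higher, 693 lower) for sg1 at day 2 and 907 genes (246 higher, 661 lower) for sg2. Without library 3 of sg1 at day 0 the counts were 3610 (1849 higher, 1761 lower) and 2754 (1129 higher, 1625 lower), and the share of sg2 calls that were higher went from 27.1% to 41.0%. The sg1 count was 731, 699 and 734 without ev libraries 1, 2 and 3, and 679 and 736 without sg1 libraries 2 and 3. The sg2 count was 596 and 566 without ev libraries 2 and 3, and 580 without sg2 library 2. Both guides shared 472 genes (80 higher, 392 lower), against 7.39 and 31.2 for independent calls, and 1623 (602 higher, 1021 lower) without library 3 of sg1 at day 0. That shared count was 287 and 288 without ev libraries 2 and 3, and 313 without sg1 library 2. The guides' changes correlated at 0.61 across genes, with a covariance of 0.198. In 20 simulations with shared ev libraries and no guide effect these were 0.50, a value set in advance as at day 0, and 0.0955. The 0 genes shared in the simulations were largely set in advance too, since few genes are called where there is no effect. As at day 0, the figures for independent calls leave the shared ev libraries out of account. At both days and with both guides 178 genes were lower and 30 higher, and 380 and 309 without library 3 of sg1 at day 0, so the imbalance was not settled.

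Cholesterol synthesis genes were lower than in ev with sg1 at day 2, in 11 of 21 (14 adjusted over the list alone) with a median of -0.88 (adjusted p = 9.84e-14; adjusted p = 0.507 with an estimated correlation). IDI1, HMGCS1 and CYP51A1, which encode enzymes of sterol synthesis, were lower, at log2 -1.31, -1.71 and -1.05. With sg2 they were lower in 2 of 21 (8 adjusted over the list alone), median -0.33 (adjusted p = 4.11e-04; adjusted p = 0.599 with an estimated correlation), with IDI1 at -0.82. S phase genes were higher with sg1 in 10 of 28 (16 adjusted over the list alone), median 0.71 (adjusted p = 3.14e-09; adjusted p = 0.574 with an estimated correlation), and GINS2 stood at 9.14 ± 1.56 TPM against 3.15 ± 1.21 in ev (SD, n = 3). Mitosis genes were higher with sg1 in 5 of 30 (8 adjusted over the list alone), median 0.73 (adjusted p = 6.85e-08; adjusted p = 0.576 with an estimated correlation). The ERK genes were higher with sg1 in 2 of 17 (3 adjusted over the list alone), median 0.45 (adjusted p = 0.00327; adjusted p = 0.576 with an estimated correlation), led by DUSP6 (1.12), and with sg2 in 3 of 17 (7 adjusted over the list alone), median 0.48 (adjusted p = 9.18e-06; adjusted p = 0.531 with an estimated correlation), led by EGR1. HIF targets were lower with sg1, with a median of -0.32 (adjusted p = 0.00327; adjusted p = 0.574 with an estimated correlation) and with sg2, at -0.29 (adjusted p = 0.00606; adjusted p = 0.531 with an estimated correlation), and CA9, which regulates pH under low oxygen, stood at -2.29 and -2.07. Mesenchymal genes were lower with sg1 in 4 of 21 (6 adjusted over the list alone), median -0.48 (adjusted p = 5.09e-04; adjusted p = 0.576 with an estimated correlation). ATF4 targets were lower with sg2, median -0.25 (adjusted p = 0.00877; adjusted p = 0.727 with an estimated correlation), a call lost without ev library 2 (0.0607) or sg2 library 1 (0.266). NRF2 targets were lower with sg1, median -0.25 (adjusted p = 0.00796; adjusted p = 0.507 with an estimated correlation), a call lost without sg1 library 1 (0.0606), and were not called with sg2 (-0.09, 0.281). With fry the sg1 calls for mitosis (0.0648), ERK (0.0623) and mesenchymal genes (0.0623) were lost, as were the sg2 calls for cholesterol synthesis (0.109), ERK genes (0.0627), HIF targets (0.0627) and ATF4 targets (0.169).

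Differences between guide cells and ev were also read along the chromosomes. Along the GRCh38 gene order, 14076 tested genes formed 235 stretches of about 60 genes, and 13 stretches had a median below -0.2 relative to all genes with both guides at both days. The lowest lay at the start of chromosome 3, from TRNT1 to GRIP2, with a mean of -0.51 over the 4 comparisons. Chromosome 20 held 4 of the 13, and the 275 genes beyond BCL2L1 on that chromosome had medians, here not relative to all genes, of -0.45 and -0.31 at day 0 and -0.33 and -0.35 at day 2 for sg1 and sg2. The medians over all tested genes were -0.11 and 0.06 at day 0 and 0.04 and 0.01 at day 2. Lower values were not confined to the part beyond BCL2L1. The first stretches of chromosome 20, C20orf96 to TMEM230 and PCNA to GINS1, were lower too. Relative to all genes they stood at -0.41 and -0.36 at day 0 and -0.51 and -0.43 at day 2 with sg1. With sg2 they lay between -0.22 and -0.17. Only 2 stretches stood above 0.2 with both guides at both days. Smaller shifts ran along whole chromosomes, and every stretch of chromosome 1 had a positive mean, up to 0.26. The guides also differed from each other. Every stretch of chromosome 5 was negative with sg1 at both days. From TARS to MIER3 the values were -0.40 and -0.28 with sg1 at day 0 and day 2, and 0.07 and 0.04 with sg2. This division of the genome was chosen after the data had been seen.

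**Figure D4:**
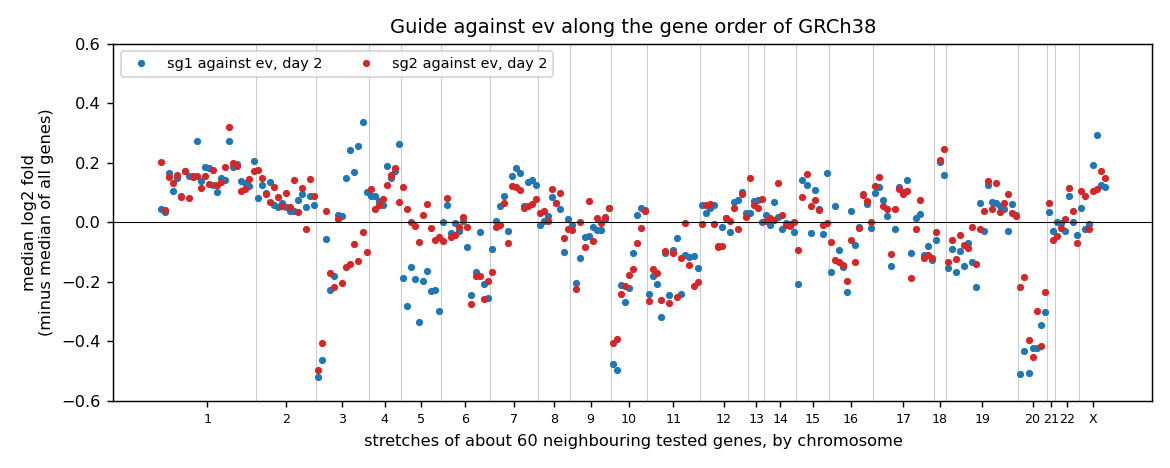
Median log2 difference from ev at day 2, relative to the median of all genes, for 235 stretches of about 60 neighbouring genes ordered along the chromosomes, for sg1 and sg2. Low stretches appear with both guides at the start of chromosome 3 and on chromosomes 10 and 20, in comparisons that share the same 3 ev libraries.

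The interactions asked whether the change over the 2 days differed between guide cells and ev. IGFBP1 rose from 10.6 ± 0.760 to 89.3 ± 9.84 TPM in ev but stayed at or below 1.75 ± 0.695 TPM with the guides (SD, n = 3 in each group), an interaction of -2.79 for sg1 (adjusted p = 6.13e-05) and -2.03 for sg2 (0.00206). C10orf10, a stress gene of autophagy, reached 108 ± 16.9 TPM in ev, 7.90 ± 2.35 in sg1 and 9.57 ± 0.540 in sg2. EGR1 rose more with both guides, by 2.46 and 3.0 on the log2 scale (0.00948 and 0.00256), and MT1M, listed at 0 in the guide cells, had -1.71 for sg1. With log2(TPM + 0.1) the interactions of IGFBP1 were no longer called (adjusted p = 0.198 for sg1 and 1.0 for sg2), nor were those of C10orf10 (0.0613 and 0.140) or of MT1M for sg1 (0.265), so these rest on the value added to the TPM. The IGFBP1 call for sg2 was also lost without the 10 highest genes (0.0544), and that of MT1M for sg1 with the filter of a TPM of 5 in 3 libraries (0.382) and with only the libraries compared (0.0597). The EGR1 calls held in these settings. Limma called 38 genes (15 higher, 23 lower) for sg1 and 35 genes (13 higher, 22 lower) for sg2, with 23 shared (10 higher, 13 lower). The guides' interactions correlated at 0.50 across genes. In 20 simulations with shared ev libraries and no guide effect the value was also 0.50, which the shared libraries set in advance. The covariance was 0.189 observed and 0.193 simulated. The 0 genes shared in these simulations were again largely set in advance. Without library 3 of sg1 at day 0 the counts for sg1, sg2 and both were 197 (56 higher, 141 lower), 129 (37 higher, 92 lower) and 72 (18 higher, 54 lower). The sg1 count was 86 without library 1 of sg1 at day 0, and 63 of its 107 calls were higher with median of ratios scaling. With log2(TPM + 0.1) only 7, 7 and 3 genes were called for sg1, sg2 and both, and with a filter of a TPM of 5 in 3 libraries 7, 9 and 5. Leaving out other libraries lowered these counts to at least 19 for sg1, 20 for sg2 and 15 shared.

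By lists, NRF2 targets rose less with both guides than in ev, with a median interaction of -0.55 for sg1 (adjusted p = 2.07e-08, and 0.0171 with an estimated correlation) and -0.63 for sg2 (7.12e-11 and 0.00453). No member was called over all genes, and 5 of 17 were with each guide when adjusted over the list alone. The interaction is the difference from ev at day 2 less that at day 0, and the list's median was 0.33 (sg1) and 0.64 (sg2) at day 0 and -0.25 and -0.09 at day 2. The day 0 difference of sg1 was unsettled, its call being lost in several settings, so the share of day 0 in the interaction is open for sg1. HMOX1 rose by 4.67 in ev, 3.58 in sg1 and 3.86 in sg2. Without library 3 of sg1 at day 0 the estimated-correlation values were 0.192 and 0.0603, no longer called. S phase genes fell less with sg1 (median interaction 1.14; adjusted p = 9.59e-18; adjusted p = 0.275 with an estimated correlation) and with sg2 (0.41; adjusted p = 2.31e-10; adjusted p = 0.564 with an estimated correlation), with 0 of 28 called over all genes and 20 for sg1 and 0 for sg2 adjusted over the list alone. The S phase interaction for sg1 was 0.87 without library 3 of sg1 at day 0. At day 0 S phase genes were lower than in ev with sg1 (median -0.42; adjusted p = 0.0312; adjusted p = 0.936 with an estimated correlation), a call lost without ev library 2 (0.0559), ev library 3 (0.0923) or sg1 library 2 (0.158), with median of ratios scaling (0.128), log2(TPM + 0.1) (0.0515) and fry (0.234), and with sg2 (-0.16; adjusted p = 0.0153; adjusted p = 0.970 with an estimated correlation), a call lost without ev library 3 (0.0589) and with fry (0.606). At day 2 they were higher with sg2 (0.12; adjusted p = 0.0195; adjusted p = 0.793 with an estimated correlation), a call lost without ev library 1 (0.504), sg2 library 2 (0.0534) or sg2 library 3 (0.519), and with fry (0.526). Mitosis genes fell less with sg1 (0.83; adjusted p = 1.43e-08; adjusted p = 0.425 with an estimated correlation). Cholesterol synthesis genes rose less with sg1 (-0.55; adjusted p = 6.30e-12; adjusted p = 0.275 with an estimated correlation) and with sg2 (-0.34; adjusted p = 3.98e-04; adjusted p = 0.692 with an estimated correlation), the sg2 call being lost without library 1 of sg2 at day 2 (0.166). Ribosomal protein genes changed to lower values with sg1 (-0.58; adjusted p = 6.73e-17; adjusted p = 0.278 with an estimated correlation) and sg2 (-0.35; adjusted p = 1.79e-07; adjusted p = 0.692 with an estimated correlation). The sg1 value rests in part on library 3 of sg1 at day 0, with its 27.4% of ribosomal protein TPM, and was -0.28 without it (adjusted p = 1.44e-06). Their change over time in sg1 went from -0.27 (adjusted p = 0.00349; adjusted p = 0.694 with an estimated correlation) to 0.10 without that library and was no longer called (0.656). The ERK genes gained with sg1 (0.50; adjusted p = 5.26e-04; adjusted p = 0.425 with an estimated correlation) and sg2 (0.43; adjusted p = 7.12e-11; adjusted p = 0.209 with an estimated correlation). With fry only the NRF2 interactions and the S phase interaction for sg1 stayed called among these, and mitosis (0.245), cholesterol synthesis (0.129 for sg1 and 0.511 for sg2), ribosomal proteins (0.204 and 0.511), ERK genes (0.205 and 0.289) and S phase for sg2 (0.511) were lost, as was the change of ribosomal proteins over time in sg1 (0.241).

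The guides were compared with each other to see how far sg1 and sg2 cells differed. Effects of the guides and other lasting differences between the cell populations are not separated here. CDH2, a mesenchymal cadherin, was 33.4 ± 3.30 TPM in sg2, 3.18 ± 1.22 in sg1 and 7.39 ± 0.774 in ev at day 0 (SD, n = 3 in each group). IFITM1, an interferon-induced membrane protein gene, was higher in sg2 than in sg1 by 3.56 at day 0 and 4.0 at day 2, and GDA, a guanine deaminase, by 3.26 and 4.25. IGFBP2 was lower in sg2, at log2 -4.45 and -4.01, while NPB, a neuropeptide gene, was listed at 0 in all sg2 libraries. Mesenchymal genes were higher in sg2 in 5 of 21 (7 adjusted over the list alone) at day 0, median 0.57 (adjusted p = 3.77e-05; adjusted p = 0.945 with an estimated correlation), and in 4 of 21 (5 adjusted over the list alone) at day 2, median 0.28 (adjusted p = 6.70e-07; adjusted p = 0.626 with an estimated correlation). Cholesterol synthesis genes were higher in sg2 at day 2 in 4 of 21 (9 adjusted over the list alone), median 0.48 (adjusted p = 5.69e-10; adjusted p = 0.626 with an estimated correlation), and S phase genes were lower, median -0.49 (adjusted p = 6.70e-07; adjusted p = 0.626 with an estimated correlation). With fry these 3 calls at day 2 were lost (0.0758, 0.0758 and 0.247). Limma called 594 genes (296 higher, 298 lower) at day 0 and 496 genes (219 higher, 277 lower) at day 2, and 936 (294 higher, 642 lower) and 1408 (607 higher, 801 lower) without library 3 of sg1 at day 0. The day 0 count was 1625 without sg1 library 1, and 324 and 353 without sg2 libraries 2 and 3. The day 2 count was 310 without sg1 library 3 and 319 without sg2 library 2. A fit of only the libraries compared called 44 genes at day 0 and 628 at day 2.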

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

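The tests on short transcripts and on BCL2L1 in library 3 of sg1 at day 0, all 5 on neighbouring genes, and that of NRF2 targets without this library were chosen after the results had been seen, and the others before.

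Library 3 of sg1 at day 0 stood apart from all other libraries, and a bias towards short transcripts, a wrong label and RNA of other cell types were weighed. Its deviations correlated with transcript length at rho = -0.302, and the most negative other library reached -0.256, but this restates the excess of short transcripts that prompted it and adds no support for a cause. An exchange with sg2 was less likely, since 71.0% of the genes called between sg2 and sg1 at day 2 lay nearer to sg1 in it, while its BCL2L1 level of 70.7 TPM spoke only against ev (158 to 209.7 TPM at day 0) and lay within the sg2 range of 57.7 to 86.1. The summed TPM of marker lists for immune, endothelial, fibroblast or neuroendocrine cells reached at most 0.478 of the highest other library. The most abundant gene of each list had a mean over all libraries of 40.7 (CD68), 2.68 (ESAM), 60.5 (COL1A1) and 5.97 TPM (SYP). Against these levels a small share of RNA from such cells would go unseen, so the sums do not decide whether any was present. Depth and RNA quality were not analysed here.

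Stretches of neighbouring genes were lower with both guides, and loss of chromosome 20 beyond BCL2L1, transcript length or GC bias and a lasting difference in chromosome copy number between cell populations are possible explanations. The most low stretches in any of 1000 shuffled gene orders was 0, against 13 found, of which 69.2% lay elsewhere than on chromosome 20 beyond BCL2L1. After correction for length and GC content 76.9% remained, close to the bound of 75% set for this test, and 92.3% remained without library 3 of sg1 at day 0. The medians of stretches at day 0 and day 2 correlated at r = 0.918, which could reflect a difference in copy number or lasting regional regulation. Loss in guide cells and gain in ev cells could not be told apart, and DNA was not analysed here.

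NRF2 targets rose less over 2 days with both guides, and the unusual library, transcript composition and scaling were weighed as possible explanations. The median interaction for sg1 was -0.58 without library 3 of sg1 at day 0, and the median for the mean of both guides was -0.57 after correction for length and GC content and -0.66 with median of ratios scaling. The 3 values suggest that none of these accounts for the median, while day 0 values were higher with sg2 (0.64) and unsettled with sg1 (0.33, call lost at 0.197 without the library), and the interaction call with an estimated correlation was lost without the library. Whether the protein NRF2 was less active was not analysed here.

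The numbers of genes whose change over time differed from ev were 38 for sg1, 35 for sg2 and 23 for both guides. Among 100 splits of the libraries, 11 gave at least as many calls as the real one for sg1 (highest other 3003) and 8 for sg2 (highest other 1813), the other splits reaching it exchanging libraries unevenly between the days. Such an uneven exchange carries the difference of the guide from ev into the interaction, so these splits do not show what chance alone gives for either guide. For both guides 1 of 100 did, the real one, with 3 as the highest other. Those splits mixed ev, sg1 and sg2 within each day, which adds the differences between the transductions to the spread. They too do not show what chance alone gives. For sg1 and sg2 the interactions were 2.46 and 3.0 for EGR1, 1.84 and 1.76 for RFTN1, and 1.54 and 1.39 for GAGE8, which was listed at 0 in both guides at day 0. They were -2.39 and -2.14 for C10orf10, -2.79 and -2.03 for IGFBP1, -1.71 and -1.71 for MT1M, and -1.55 and -1.53 for MLPH. For OSCAR they were -1.69 and -1.45, the sg2 call being lost in 8 of 12 leave-one-out fits (adjusted p up to 0.0893), and for RGS3 -1.41 and -1.74, the sg1 call being lost in 10 (up to 0.144). NNMT gave -1.38 and -1.34, lost in 3 for sg1 (up to 0.0707) and 8 for sg2 (0.0741), and RASSF4 gave -1.23 and -1.30, lost in 11 each (0.136 and 0.130). With log2(TPM + 0.1) only EGR1 and MLPH kept both calls, OSCAR kept that for sg1 and RGS3 that for sg2, and those lost were at 0.0613 (C10orf10, sg1) or above.

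List medians of the interaction for sg1 were -0.13 for HIF targets, -0.15 for ATF4 targets, -0.55 for cholesterol synthesis, -0.18 for respiratory chain subunits, 1.14 for S phase, 0.83 for mitosis, -0.58 for ribosomal proteins, 0.50 for ERK genes, -0.22 for antigen presentation and -0.55 for NRF2 targets. For sg2 they were -0.31 for HIF targets, -0.16 for glycolysis, -0.29 for ATF4 targets, -0.34 for cholesterol synthesis, 0.41 for S phase, -0.35 for ribosomal proteins, 0.43 for ERK genes and -0.63 for NRF2 targets. With an estimated correlation only the NRF2 calls held (adjusted p = 0.0171 and 0.00453), and the other lists were at 0.275 to 0.696 for sg1 and 0.209 to 0.851 for sg2, the ATF4, glycolysis and respiratory chain calls among those lost. With the preset correlation the ATF4 call was lost in 5 of 11 leave-one-out fits for sg1 (adjusted p up to 0.130) and without library 1 of sg2 at day 2 for sg2 (0.331). The glycolysis call for sg2 was lost in 5 of 12 (up to 0.10), and the sg1 call for respiratory chain subunits in 2 of 11 (up to 0.0717). In the remaining fit, without library 3 of sg1 at day 0, the median for respiratory chain subunits was 0.01 and the direction reversed (0.286), while the ATF4 call held (0.0281).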

How the results depend on the processing

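The fit without library 3 of sg1 at day 0, the same with scaling, and gene-by-gene library weights were chosen after the results had been seen. The fit of the planned library weights did not converge. Its weights ran from 0.0045 (library 3 of sg1 at day 0) to 76.5 (library 2 of sg2 at day 2), and the gene-by-gene weights replaced them. For the shared interaction of both guides the fit of only the libraries compared gave no value. Counts below are genes called, the cause of a shift was not tested unless stated, and values are in the order ev, sg1, sg2 for day 2 against day 0.

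Day 2 against day 0 gave 5168, 5524 and 4786 genes. Library weights gave 9352 in ev and 10287 in sg2. Leaving library 3 of sg1 at day 0 out of every fit gave 8082 in ev and 7665 in sg2, and 8718 and 8365 with median of ratios scaling as well. Because the library lies in neither comparison, the shifts to 8082 and 7665 came through the shared spread, while scaling alone gave 6180 and 5795. Only the libraries compared gave 8400 in ev and 1210 in sg1. A log2 fold of at least 1 left 2251, 2347 and 2040.

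Against ev at day 0 the counts were 1718 for sg1 and 708 for sg2. Library weights gave 4588 and 5373, scaling gave 1171 for sg2, and the library left out gave 2377 for sg2 (3024 for sg1). With scaling as well these were 3096 and 3020. Only the libraries compared gave 142 and 3286, a log2 fold of at least 1 gave 635 and 342, and the stricter filter, a TPM of 5 in 3 libraries, gave 415 for sg2. At day 2 the counts were 1134 and 907. Library weights gave 4140 and 5307, scaling 1817 and 1451, the library left out 3610 and 2754, and with scaling as well 4502 and 3717. Only the libraries compared gave 2581 and 1665, a log2 fold of at least 1 gave 420 and 380, and the stricter filter 677 and 475.

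With a library left out in turn, sg1 against ev at day 0 ran from 824 (ev library 3) to 3229 (sg1 library 1), and sg2 from 430 (sg2 library 2) to 517 (sg2 library 3). At day 2 sg1 ran from 679 (sg1 library 2) to 780 (sg1 library 1), and sg2 from 566 (ev library 3) to 768 (sg2 library 3). Both guides shared 236 without ev library 3 to 1405 without sg1 library 3 at day 0, and 287 without ev library 2 to 404 without sg2 library 3 at day 2.

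The interactions counted 38 for sg1, 35 for sg2 and 23 for both. With log2(TPM + 0.1) they were 7, 7 and 3, with the stricter filter 7, 9 and 5, and without the 10 highest genes 20, 20 and 12. No filter gave 55 for sg2 and 35 for both. Scaling gave 107 for sg1 and 35 for both, and library weights 597, 1210 and 312. The library left out gave 197, 129 and 72, with scaling as well 299, 156 and 94, and only the libraries compared 11 and 105. With a library left out in turn sg1 ran from 19 (ev library 2 at day 0) to 197, sg2 from 20 to 31 (ev library 3 at day 2), and both from 15 (ev library 2 at day 0) to 72.

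Between the guides 594 genes were called at day 0 and 496 at day 2. Library weights gave 2381 and 2794, scaling 985 and 808, the library left out 936 and 1408, and with scaling as well 1204 and 1925. Only the libraries compared gave 44 at day 0, a log2 fold of at least 1 gave 312 and 276, and the stricter filter 356 and 256. With a library left out in turn these ran from 324 (sg2 library 2) to 1625 (sg1 library 1) at day 0 and from 310 (sg1 library 3) to 394 (sg2 library 3) at day 2. Both guides shared 409 and 472 genes against ev. Library weights gave 2885 and 2427, scaling 711 and 757, the library left out 1405 and 1623, and with scaling as well 1680 and 2295. Only the libraries compared gave 162 and 1079, a log2 fold of at least 1 gave 165 and 161, and the stricter filter 234 and 241.

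The balance of higher and lower calls moved too. Without the 10 highest genes the calls were 4319 higher and 1376 lower over time in sg1, 168 and 506 for sg2 at day 0, 14 and 6 for the interaction of sg1, and 354 and 200 between the guides at day 0. Scaling gave 543 higher and 908 lower for sg2 at day 2, and 63 and 44 for the interaction of sg1. With the library left out as well, scaling gave 3767 and 3752 over time in sg1, 2217 and 2285 for sg1 at day 2, 1783 and 1934 for sg2 at day 2, 149 and 150 for the interaction of sg1, and 985 and 1310 for both guides at day 2. Library weights gave a majority higher at day 0 for sg1 (2706 and 1882), sg2 (3212 and 2161) and both (1702 and 1183).

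BCL2L1 stayed lower with the guides and at day 2 in every setting. Its difference for sg1 at day 0 ran from -1.49 without the 10 highest genes to -1.04 with scaling, and its change over time in sg1 from -1.02 with scaling to -0.58 without the 10 highest genes. With only the libraries compared 2 of its calls were lost, that of sg1 against ev at day 0 (-1.20, adjusted p = 0.0604) and that over time in sg1 (-0.79, 0.0574). With a library left out in turn its log2 difference from ev ran from -1.31 to -1.11 for sg1 and -1.48 to -1.19 for sg2 at day 0, and from -1.17 to -0.91 and -1.31 to -1.06 at day 2. Residuals of libraries with the same replicate number correlated at a median of -0.0029 over all pairs (-0.108 to 0.165). Among libraries of other groups, 9 of 18 lay nearest to one of their own number. At day 2 deviations from group mates followed GC content alike by number. For ev, sg1 and sg2 rho was -0.36, -0.16 and -0.20 in library 1, and 0.44, 0.12 and 0.25 in library 2. In ev at day 0 these were -0.16 and 0.20, without such a pattern in sg1 or sg2. A step shared by number is not excluded.

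Of 286 list tests 117 were called with the preset correlation, 8 with an estimated correlation, 78 with fry and 124 with the library left out, of which 3 with an estimated correlation. With a library left out in turn 110 to 122 were called. In 2 cases the direction reversed and the call was lost without library 3 of sg1 at day 0: ribosomal proteins over time in sg1 (adjusted p = 0.656) and respiratory chain subunits in the interaction of sg1 (0.286). Scaling ended 3 of the list calls reported, ribosomal proteins over time in ev (0.299) and, for sg1 at day 0, NRF2 targets (0.102) and S phase genes (0.128). The stricter filter ended those of NF-kB genes over time in ev (0.0515), antigen presentation over time in sg2 (0.0595) and NRF2 targets for sg1 at day 0 (0.0590). Over the other settings list results kept their call state and direction in 1758 cases, lost a call in 200 and gained it in 42, and with a library left out in turn in 1811, 67 and 46. Named genes did so in 8717, 454 and 104 cases, and with a library left out in turn in 5346, 643 and 11.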

Other observations

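The tests of the genes lower with both guides and of the splits were chosen before the results were seen.

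Other BCL2 family genes changed over the 2 days as well. MCL1, an anti-apoptotic member like BCL2L1, rose by 0.79 in sg1 (adjusted p = 0.0334) and 0.75 in sg2 (0.0461) and was not called in ev (0.26, 0.495). The difference from ev was not called either (0.53, 0.751 for sg1, and 0.49, 1.0 for sg2). BCL2A1, another anti-apoptotic member, fell by 3.02 in ev, 2.67 in sg1 and 2.73 in sg2. For MCL1 no library was left out in turn.

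Marker lists with few tested members were read gene by gene. The collagen COL3A1 was lower with sg1 and sg2 than in ev at day 0 (-1.38 and -1.53) and day 2 (-1.26 and -1.37). The surface glycoprotein THY1 was lower with sg2 (-2.53 at day 0 and -1.84 at day 2), was not called with sg1 (-0.26, adjusted p = 0.522 at day 0, and 0.37, 0.459 at day 2) and fell over time in ev (-0.71). COL1A1 was called neither over time nor between guide cells and ev. The endothelial gene ESAM was lower with sg1 at day 0 (-1.17, 0.00665) and fell over time in ev (-0.89, 0.0105). SYP, a synaptic vesicle gene, rose over time by 0.84 in ev, 0.69 in sg1 and 0.77 in sg2, and SCG2 rose by 1.11, 0.69 and 1.89. SCG5 was called over time only in sg2 (-0.69, 0.00779), but the difference of this change from ev was not called (-0.84, adjusted p = 0.474). CHGB was not called over time, and the lysosomal gene CD68 fell by 0.83, 1.16 and 0.90. With sg1 SCG2 was lower than in ev at day 0 (-1.03, 0.0121) and day 2 (-1.45, 0.00120), and CHGB at day 0 (-0.69, 0.0230). Of the immune list 1 of 12 members was tested, of the endothelial list 1 of 10 (ESAM), of the fibroblast list 3 of 10, of the neuroendocrine list 4 of 13, of the anti-apoptotic list 3 of 5 and of the mitochondrial genome list 0 of 13. MIR6723 held between 14.0% and 34.3% of the TPM of a library.

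Of the genes lower with both guides at day 2, 2.88% lay on chromosome 20 beyond BCL2L1, where 1.95% of the tested genes lay. The 13 low stretches of neighbouring genes held 17.5% of the lower genes, against 5.47% of the tested genes with a known place. Those stretches were picked from the same differences after the data had been seen, so this share is no separate test. After correction for transcript length and GC content 90.1% of the genes lower with both guides, among those with a known length, were still called so. The correction also changed the number and balance of the calls. At day 2 it gave 673 genes lower and 310 higher with both guides, against 392 and 80 without it over all tested genes.

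Only 10 splits exist for 3 against 3 libraries, too few for a test, and in each such comparison 1 split gave a count as large as the real one, the real split itself. For day 2 against day 0 the real counts of 5168 in ev, 5524 in sg1 and 4786 in sg2 stood against 2, 858 and 1 as the highest of the other splits. For sg1 and sg2 against ev they were 1718 and 708 at day 0, against 1 and 1, and 1134 and 907 at day 2, against 2 and 2. Between the guides they were 594 and 496, against 1 and 3. For both guides 1 of 100 splits, the real one, gave as many genes at day 0 (409, highest other 348) and at day 2 (472, highest other 157). The other splits mixed ev, sg1 and sg2 libraries, so the differences between the transductions entered the spread and lowered the calls.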
